A study of Mus musculus with 3 samples.

How the data were processed

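The series measured RNA in reporter-positive cells sorted from superior cervical ganglia of mice. Per the labels' protocols, live cells positive for yellow fluorescent protein were collected by fluorescence-activated sorting and made into Smart-Seq2 libraries, a method that copies full-length RNA and amplifies the cDNA by PCR. The protocol text calls the mice a LepR reporter line and the genotype label gives LepRCRE::Ai32. The 3 libraries are labelled biological replicates of 1 group, so n = 3 throughout, and their replicate numbers come from the labels. How many cells or animals went into a library is not given in the sources used here.

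The authors deposited log2 TPM for 52550 genes in the 3 libraries, and in linear scale each column sums to 1000000. Per the submitters' processing notes, STAR and featureCounts were used with the build mm10 (GRCm38). Their versions, the annotation release, the strand setting, any filter and the step from counts to TPM are not given in the sources used here. The deposited log2 TPM values are relative to gene length and to the library total, so a gene that takes more of a library lowers all others. Mitochondrially encoded genes alone took from 19.88% to 21.12% of it.

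The values showed that 0.25 read had been added to each gene before division by its length, which no label states. With exon lengths from GENCODE M21, an annotation of the same build, whole reads per gene could therefore be recovered. All 49035 genes whose versioned ID is in M21 came out whole in every library within 0.02 of a read, 49791 genes did so with an M21 length of any ID version, and 2328 more did so with a length solved from the values. Reads were thus recovered for 52119 genes (99.18%) and not for 431, and 147 IDs were not in M21. The recovered totals were 8295136, 8088855 and 7706901 reads. Because of the added 0.25 read every value exceeds 0, so the planned filter, a value above 0 in at least 1 library, was read as at least 1 recovered read in at least 1 library. It kept 27513 genes and left out 25037. The value of a library without a read holds only the added 0.25 read, so reads are printed in its place. For a named gene without a read in any library, other than the Y-linked genes, the level of 3 reads is given. Means, SDs and tests use the values as deposited. Reads are PCR copies without molecular identifiers, so such floors cover counting error only. The tests of genes, lists and pairs used TPM. The recovered reads served to find genes with a read, to describe depth and to weigh explanations in the closing section.

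For each gene, mean log2(TPM + 1) was tested against its value at 1 TPM with limma's moderated test (limma 3.58.1, R 4.3.3, two-sided, prior degrees of freedom 1.13), with Benjamini-Hochberg adjustment over 27513 genes and a threshold of 0.05. Differences on this scale understate those of low genes. Adjusted p-values of many genes share a value, 0.0434, set by the adjustment. Counts per gene list are given over all genes tested and adjusted over the list alone. The median of the perineurial list was compared with that of 13 other cell-type lists, genes in both left out, by a two-sided permutation of genes between the lists (100000 resamples, Benjamini-Hochberg over 13 comparisons) and by an exact two-sided sign-flip test over libraries, whose smallest p is 0.25. The permutation took each gene's mean over libraries, whereas the differences printed are means of the differences within libraries. Genes of a list are not independent, so the permutation describes these lists in these libraries. Percentiles came from 10000 random lists of the same size. Other work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and matplotlib 3.10.9 for figures.

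On simulated data, with 50 genes moved at each size among 27513 and each gene's own spread, limma's test recovered 48% of genes moved by 8 on the log2 scale, 34% of those moved by 4 and 0% of those moved by 2, with 0 false calls. With spreads drawn from the fitted prior it recovered 60% at 8 and 0% at 4. With many genes moved and each gene's own spread (2287, 2265, 2265 and 2354 genes by -2, 2, 4 and 8), limma's test recovered 65.6%, 65.6%, 82.4% and 93.8%. Of 7361 calls, 301 (4.09%) were false. No gene can lie as far below the tested level as -2 on the scale used, so that rate does not describe calls below it. Low genes lent small spreads, such as the SD of 0.044 of Mpzl2. Genes with a mean of at least 5 TPM had a median SD of 1.72 on a log2 scale. The rates with each gene's own spread may therefore overstate recovery of such genes. The list permutation, on lists of 16 and 12 genes, gave p under 0.05 in 4.0% of 200 simulations with no shift and in 100% with a shift of 4. Both simulated lists were drawn at random from the same 27513 genes, so a rate near the threshold with no shift was fixed in advance. Genes of the real lists are not independent, so these rates need not hold for them.

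Before the data were examined, 28 lists were fixed: perineurial cells, fibroblasts, epineurial and endoneurial fibroblasts, sympathetic neurons, satellite glia and Schwann cells, endothelium, mural cells, macrophages, lymphocytes, mast cells and neutrophils, adipocytes, erythroid cells, arachnoid barrier cells, tight junctions, adherens and gap junctions, basement membrane and integrins, leptin signalling, barrier transporters, neurotransmitter receptors, neurotrophic and growth factors, hedgehog signalling, cytokines and chemokines, antigen presentation, immediate early and heat shock genes, cell cycle, housekeeping genes, and Xist with Y-linked genes. Of the 16 perineurial genes, 6 are also in another of the lists. A further 8 lists were added after the data were seen. The rule for named genes, also fixed beforehand, took Lepr, the 20 genes with the highest mean log2(TPM + 1) other than mitochondrially encoded and ribosomal protein genes, every perineurial gene, the 4 highest and the first-written member of each other list, receptors above 1 TPM, the members of 7 gene pairs, the 5 genes with the largest SD at a mean of at least 5 TPM, and Xist with the Y-linked genes. Some genes this rule takes, and 4 of the 7 pairs, are not reported here. Npy, Tsix, X-linked homologues and members of the added lists were named after their values were seen, and so was the choice of genes drawn in the plot of markers.

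Alternatives were a pseudocount of 0.1, leaving out genes with a mean under 0.5 TPM, rescaling without mitochondrially encoded genes, each replicate left out in turn, levels of 5 and 0.5 TPM, a mean-variance trend in limma, at least 1 TPM in all 3 libraries with no test, list means in place of medians, the perineurial list without Tjp1, Ocln and Ptch1, and percentiles among genes above 1 TPM. TPM recomputed from the recovered reads with nothing added was tried after the data were seen. Genes with near-identical copies (Hspa1a and Hspa1b, H2-K1 and H2-D1, Ly6c1 and Ly6c2) and genes overlapping on the other strand are uncertain, since how the authors counted shared reads is not given in the sources used here.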

Results

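RNA was measured in reporter-positive cells sorted from the superior cervical ganglion, the sympathetic ganglion of the upper neck, of mice aged 10 weeks. The mice carried Cre recombinase at the leptin receptor gene (Lepr) and Ai32, a Cre-dependent reporter that makes a channelrhodopsin fused to yellow fluorescent protein. The labels give 3 biological replicates in 1 group of LepR+ cells, and the series title calls the cells perineurial, the barrier cells that wrap peripheral nerve. With no second group, the design implied 3 questions: which genes lay above a fixed level, how markers of perineurial cells compared with markers of the other cell types of a ganglion, and how closely the replicates matched. The values were log2 TPM, from which 8295136, 8088855 and 7706901 reads on genes were recovered for replicates 1, 2 and 3, with at least 1 read on 17735, 18329 and 18852 genes. On a gene of 1 kb, 1 read was worth 0.391, 0.391 and 0.418 TPM. Mitochondrially encoded genes took 19.88%, 20.37% and 21.12% of TPM.

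Lepr (ENSMUSG00000057722.17, chromosome 4, 101717404 to 101815352 of GRCm38, forward strand), the gene at which the mice carried Cre, was read in all 3 libraries, at 363, 32.1 and 54.0 TPM from 6531, 578 and 911 reads. Its mean of 149.6 ± 185 TPM (SD, n = 3) was above 1 TPM by 5.44 on the log2(TPM + 1) scale (limma, adjusted p = 0.0434). That call was lost without any 1 of the replicates, with adjusted p = 0.0796, 0.103 and 0.171 in limma's test without replicates 1, 2 and 3.

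The 20 most abundant genes, leaving out mitochondrially encoded and ribosomal protein genes, were led by Fabp7 (chromosome 10, 57784881 to 57788450), a fatty acid binding protein of glial cells, at 14163 ± 1886 TPM (SD, n = 3). Apoe, a lipid carrier made by satellite glia and macrophages, followed at 8934 ± 772 TPM. The adhesion gene Cdh19, which marks Schwann cell precursors and peripheral glia, stood at 4129 ± 873 TPM, and the matrix proteoglycan Dcn, a fibroblast product, at 3791 ± 634 TPM. The membrane protein genes Gpm6b and Cd9 had 2890.0 ± 203 and 2992 ± 371 TPM. The lipid genes Scd1, Abca8a, Apod and Dbi had means of 2564, 2396, 2449 and 4356 TPM. Cst3, B2m, Sat1, Fth1, Malat1, Itm2b and Calm2 made up the rest of the genes with an established name, at 7198, 5422, 4779, 4269, 4050.0, 3929 and 2452 TPM. The remaining 3, Gm10800, CT010467.1 and Gm23935, annotated as a protein-coding gene, an rRNA and a miRNA, had 8554, 5811 and 4098 TPM. Whether their reads were placed rightly is uncertain and was not tested. All 20 lay above 1 TPM (limma, adjusted p from 0.00357 to 0.00379).

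Over all 27513 genes with a read, limma called 4519 above 1 TPM, 4139 of them protein coding, and 5092 below it, with 17902 called neither. At least 1 TPM and a read in each library was reached by 6496 genes. Without replicate 1 limma called 0 genes above, and 4643 at an unadjusted p under 0.05. Without replicate 2 it called 0, and 4447 unadjusted, and without replicate 3 it called 2451. Without replicate 1 or 2, without mitochondrially encoded genes or at a level of 0.5 TPM, it called 0 genes below. Counts of list members below, given next, are therefore also 0 in those settings.

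Of the 16 perineurial genes fixed before the data were examined, 4 lay above 1 TPM, 2 below, 9 passed neither way and 1 had no read. Adjusted over the list alone, 5 were above and 2 below. The 4 were Cldn1 (chromosome 16, 26356642 to 26371841), a claudin of the perineurial barrier, at 227 ± 15.9 TPM, Sfrp5, a secreted Wnt inhibitor, at 91.1 ± 14.3, Ptch1, the hedgehog receptor, at 90.0 ± 30.1, and Tjp1, a scaffold of tight junctions, at 46.1 ± 15.8 (SD, n = 3; limma, adjusted p from 0.00357 to 0.00625). Other members were high in 1 or 2 libraries. Itgb4, the laminin-binding integrin of perineurial cells, had 0.851, 32.1 and 1.15 TPM (adjusted p = 0.400), and Slc2a1, a glucose transporter of blood-nerve barriers, had 1.59, 34.0 and 0.507 TPM (adjusted p = 0.408). Ocln, another tight junction protein, had 54.1, 0.116 and 0.421 TPM, Lypd2 4.76, 93.4 and 30.3 TPM, Wnt6 3.62, 59.6 and 1.19 TPM, Adamtsl3 6.38, 29.9 and 111 TPM, and Stxbp6 0.757, 3.12 and 68.6 TPM. Moxd1 had no read in replicate 1 and 47.1 and 37.8 TPM in the others, and Dleu7 had 58 reads in replicate 2 and none elsewhere. Msln and Mpzl2 lay below 1 TPM with 1 read each, and Krt19 had no read, where 3 reads would be 0.633, 0.632 and 0.676 TPM. A mean-variance trend in limma raised the count of members above 1 TPM from 4 to 7, and leaving out replicate 1 or replicate 2, where no gene passed, took it to 0.

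Glial markers were the highest of the 14 cell-type lists. Of 14 satellite glial and Schwann genes, 12 lay above 1 TPM and 1 below, likewise 12 and 1 adjusted over the list alone. Fabp7, Apoe and Cdh19 led it, and together the list took 3.21% ± 0.275 of TPM (SD, n = 3), against 0.0667% ± 0.0141 for the perineurial list. Fibroblast genes followed, with 7 of 12 above 1 TPM (8 adjusted over the list alone) and 5 neither: after Dcn, the proteoglycan Lum had 1618 ± 849.5 TPM, the collagens Col3a1 and Col1a2 had 219.8 ± 76.5 and 109 ± 16.7, and Pdgfra, a receptor of fibroblasts, had 31.2, 2.66 and 7.06 (adjusted p = 0.101). Of 12 epineurial fibroblast genes, 3 were above (4 above and 1 below adjusted over the list alone) and 4 had no read, Pi16 among them, for which 3 reads would be 0.294, 0.294 and 0.314 TPM. Ly6c1, Ly6a and Mfap5 were those above, at 422 ± 90.2, 395 ± 127 and 40.7 ± 15.6 TPM, and Cd34 had 7.96, 133 and 31.8. Ly6c1 has a near-identical copy, so its value is uncertain. Of 10 endoneurial fibroblast genes, 3 were above and 1 below (3 and 2 adjusted over the list alone), with Apod and Abca8a at the means given above, Etv1 at 44.2 ± 34.3 and Sox9 at 2.95 ± 2.78.

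Vessel genes were present, at lower levels than the leading glial genes. Of 12 endothelial genes, 3 were above 1 TPM, also adjusted over the list alone, and 9 reached 1 TPM in all 3 libraries: Emcn, a sialomucin of capillaries and veins, had 173 ± 56.2 TPM (SD, n = 3), Tek 46.6 ± 33.7 and Flt1 38.6 ± 14.7, while Pecam1 had 4.92, 40.2 and 5.12 and Kdr 4.95, 10.7 and 45.6. Of 12 mural genes, 5 were above and 1 below (5 and 2 adjusted over the list alone), among them Rgs5 at 128 ± 95.8 TPM, Mcam at 76.4 ± 64.1, Acta2 at 70.4 ± 76.5 and Abcc9 at 22.2 ± 7.93. Of 10 arachnoid barrier genes, 3 were above and 1 below (3 and 3 adjusted over the list alone): the efflux transporters Abcg2 and Abcb1a had 165 ± 68.5 and 53.4 ± 32.9 TPM and the cadherin Cdh1 7.65 ± 5.03, while Crabp2 had 130, 0 and 1 reads.

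Neuronal and immune markers were low by list median, but single members were high in 1 or 2 libraries. Of 17 sympathetic neuron genes, 2 were above 1 TPM and 1 below, also adjusted over the list alone. Th, the rate-limiting enzyme of catecholamine synthesis, had 0, 1 and 4 reads, and Npy, a co-transmitter of sympathetic neurons, had none, where 3 reads would be 2.07, 2.07 and 2.21 TPM. Among those above was Slc18a2, the vesicular monoamine transporter, at 122 ± 139 TPM (SD, n = 3). Hand2 had 12.5, 0.706 and 6.26 TPM, and Tubb3 had 0, 243 and 1 reads, which was 50.9 TPM in replicate 2. Of 14 macrophage genes limma called 0 above 1 TPM and 2 below (0 and 0 adjusted over the list alone), with 0 above at an unadjusted p under 0.05 and 0 with a mean-variance trend. Csf1r had 0.260, 0.420 and 0.620 TPM, Ptprc 0.0695, 1.90 and 11.1, and Lyz2 0.372, 2.15 and 13.7, while Tyrobp had 0, 33 and 120 reads and Cd68 0, 196 and 0 reads. In TPM, Tyrobp had 19.5 and 75.3 in replicates 2 and 3, and Cd68 had 61.0 in replicate 2. Of 12 lymphocyte genes limma called 0 above and 5 below (0 and 6 adjusted over the list alone; 0 above unadjusted or with a trend), and 6, Trbc2 and Nkg7 among them, had no read, where 3 reads would be 1.70, 1.69 and 1.81 TPM for Trbc2 and 1.28, 1.28 and 1.37 TPM for Nkg7. Of 12 mast cell and neutrophil genes it called 0 above and 1 below (0 and 0 adjusted over the list alone; 1 above unadjusted, 0 with a trend), with Kit at 8.47 ± 6.75 TPM. Of 5 erythroid genes it called 0 either way, also adjusted over the list alone, unadjusted or, for calls above, with a trend, and Alas2 had 200, 2 and 0 reads. Of 10 adipocyte genes 1 was above and 2 below (1 and 5 adjusted over the list alone): Fabp4, also made by capillary endothelium, had 31.2 ± 11.3 TPM, and Adipoq had 0, 1 and 0 reads.

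**Figure D1:**
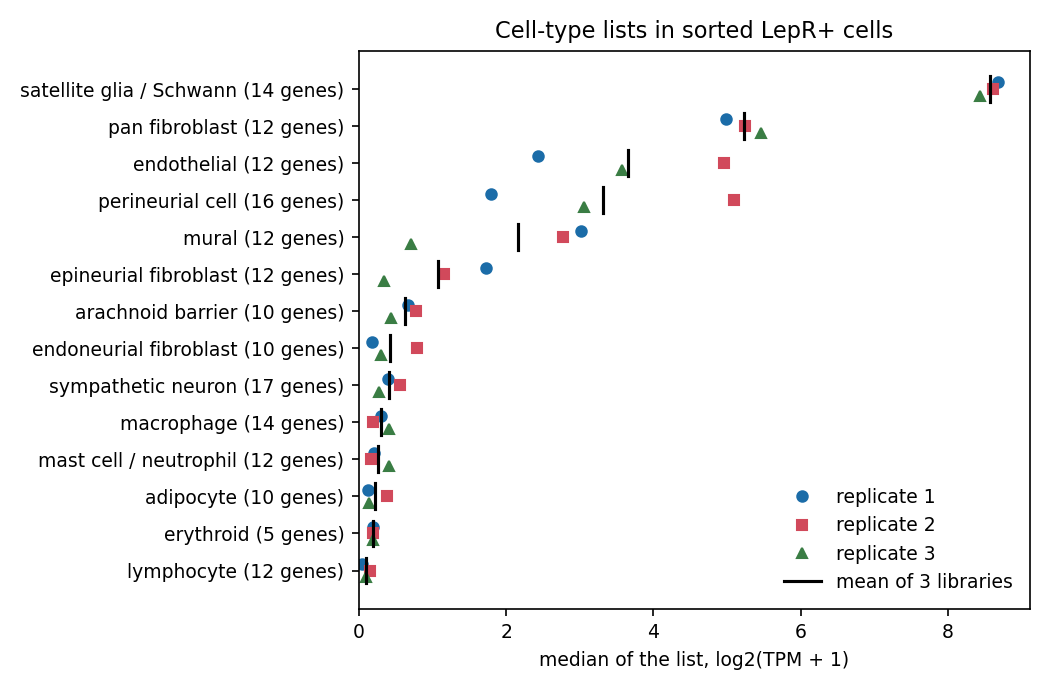
Median log2(TPM + 1) of each of the 14 cell-type lists, with 1 point per replicate and a line at the mean of the 3 libraries. The satellite glial and Schwann list lies at 8.57, the perineurial list at 3.31 with its points between 1.79 and 5.09, and the sympathetic neuron list at 0.41.

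**Figure D2:**
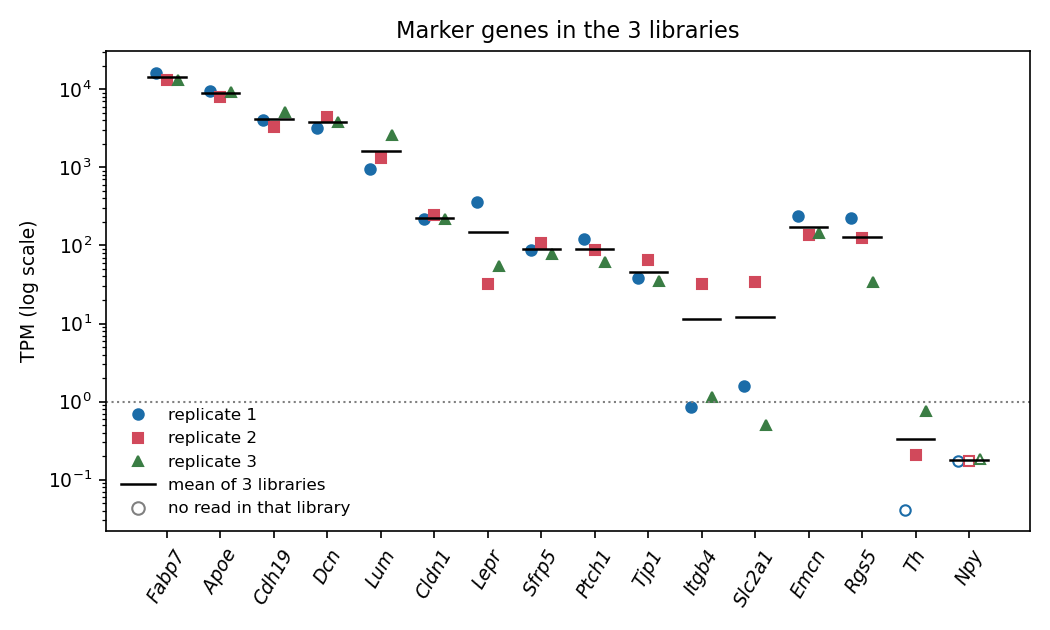
TPM of selected marker genes in each library on a log axis, with points for replicates, a line at the mean of the 3 libraries, a dotted line at 1 TPM and open points, at the value of the added 0.25 read, where a library had no read. Fabp7 has a mean of 14163 TPM and Cldn1 of 227 TPM, while Npy has no read in any library.

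The median of the perineurial list, 3.31 in log2(TPM + 1), was below that of the glial list (difference -5.26 ± 1.69, SD, n = 3; permutation of genes between the lists, adjusted p = 0.00494), in 3 of 3 libraries. It was above the neuron list by 2.90 ± 1.57, the macrophage list by 3.01 ± 1.73 and the lymphocyte list by 3.21 ± 1.61 (permutation, adjusted p = 0.0279 for each), and above the mast cell and neutrophil list by 3.05 ± 1.71 (permutation, adjusted p = 0.0316), each in 3 of 3 libraries. The fibroblast list lay above it (-1.92 ± 1.58) and the endothelial list near it (-0.34 ± 0.42), and neither difference passed the permutation test (adjusted p = 0.204 and 0.662). The epineurial, endoneurial, mural and arachnoid lists lay below it by 2.24 ± 1.98, 2.89 ± 1.35, 1.14 ± 2.05 and 2.68 ± 1.60, and the adipocyte and erythroid lists by 3.09 ± 1.53 and 3.12 ± 1.67, none past the threshold (permutation, adjusted p = 0.214, 0.169, 0.518, 0.199, 0.0978 and 0.169). The value permuted was the difference between medians of gene means, perineurial minus other. It was -5.59 for the glial, 1.78 for the arachnoid and 2.65 for the erythroid list. Over the 3 libraries the exact sign-flip test cannot go below p = 0.25, and it gave 0.25 for 11 of the 13 lists and 0.5 for the endothelial and mural lists. The differences from the neuron, macrophage and mast cell lists missed the permutation threshold when genes with a mean under 0.5 TPM were left out (adjusted p = 0.568, 0.522 and 0.309), and that filter turned the direction of the epineurial, endoneurial and endothelial differences, to -0.78, -3.66 and 0.78. Without replicate 2 those 3 and the lymphocyte list missed it (permutation, adjusted p = 0.107, 0.0565, 0.107 and 0.0533).

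Among 10000 random lists of genes with a read, the median of the members with a read lay at percentile 99.87 for the perineurial list, 100 for glia, 99.98 for fibroblasts, 98.18 for epineurial and 67.56 for endoneurial fibroblasts. The percentile was 99.26 for endothelial, 96.46 for mural, 44.98 for arachnoid and 30.12 for neuron genes. Macrophage, lymphocyte, mast cell and neutrophil, adipocyte and erythroid genes lay at percentile 20.77, 0.12, 8.70, 6.81 and 30.29. Members without a read do not enter, which favours lists such as the epineurial one.

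Of 31 tight junction genes, 6 were above and 8 below (6 and 9 adjusted over the list alone) and 6 had no read. Cldn1 was the claudin among the 6. Jam2, Jam3 and F11r, junctional adhesion molecules, had 246 ± 58.5, 103 ± 46.8 and 53.1 ± 33.3 TPM (SD, n = 3). Of 19 adherens and gap junction genes, 9 were above and 2 below (9 and 3 adjusted over the list alone): the catenins Ctnna1 and Ctnnb1 had 449 ± 163 and 256 ± 57.7 TPM, Gjc3, a connexin of glial cells, 205 ± 57.2, and Cdh11, a mesenchymal cadherin, 91.4 ± 17.2. Of 24 basement membrane and integrin genes, 14 were above and 2 below (14 and 3 adjusted over the list alone), with Nid1 at 339.6 ± 94.9 TPM, Itgb1 at 296 ± 103, Itga6 at 125 ± 28.8, Lamb1 at 121 ± 19.9 and Col4a1 at 55.7 ± 33.5. Of 20 barrier transporter genes, 8 were above and 1 below, also adjusted over the list alone: besides Abcg2, the amino acid transporter Slc38a2 had 312 ± 233 TPM, the water channel Aqp1 156 ± 118 and the anion transporter Slco1a4 83.1 ± 29.9. The medians of the tight junction, adherens and gap junction, basement membrane and transporter lists lay at percentile 25.75, 100, 100 and 99.89 of random lists.

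Of 14 leptin signalling genes, 5 were above 1 TPM and 0 below (6 and 0 adjusted over the list alone; 0 below at an unadjusted p under 0.05), at percentile 98.00. Apart from Lepr these included Pik3r1, a regulatory subunit of PI3-kinase, at 253 ± 73.0 TPM and Jak2, the kinase bound to the receptor, at 113 ± 32.5 (SD, n = 3). Stat3, which the receptor activates, had 5.47, 64.8 and 60.8 TPM (limma, adjusted p = 0.0539).

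Receptors for sympathetic transmitters were mostly low. Of 22 neurotransmitter receptor genes, 1 was above and 9 below 1 TPM, also adjusted over the list alone, 4 had no read, and the median lay at percentile 0.91. P2rx4, an ATP-gated channel, was the 1 above, at 25.7 ± 11.4 TPM (SD, n = 3; limma, adjusted p = 0.0187). P2ry1 had 0, 497 and 181 reads, Adra2c 9.12, 20.1 and 0.152 TPM, and Adra1a was below at 0.163 ± 0.0654. Adrb1 and Adrb3 had no read, where 3 reads would be 0.471, 0.471 and 0.503 TPM for Adrb1 and 0.348, 0.347 and 0.371 TPM for Adrb3.

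Of 21 neurotrophic and growth factor genes, 3 were above and 6 below 1 TPM (4 and 6 adjusted over the list alone) and 6 had no read, with the median at percentile 23.01. The heparin-binding factors Ptn and Mdk and the growth factor Fgf2 were those above, at 709 ± 245, 50.7 ± 32.1 and 94.0 ± 38.8 TPM (SD, n = 3), and Vegfa had 11.1 ± 7.63 TPM (adjusted p = 0.0585). Bdnf had no read, where 3 reads would be 0.189, 0.189 and 0.202 TPM. Of 14 hedgehog genes, 2 were above and 2 below, also adjusted over the list alone, at percentile 88.02: Ptch1, and Dhh, the ligand that Schwann cells send to the forming perineurium, at 62.7 ± 16.4 TPM. Smo had 2.87, 17.8 and 50.7 TPM and Sufu 24.6, 19.5 and 0.316. Of 18 cytokine and chemokine genes, 4 were above and 3 below (5 and 3 adjusted over the list alone), at percentile 96.30: the eosinophil attractant Ccl11 had 1040.0 ± 409.5 TPM, Il34, a ligand of the macrophage receptor, 124 ± 47.9 and Cxcl12 35.9 ± 10.8, while Il33 had 117 ± 157 (adjusted p = 0.0614), and Il6 had no read, where 3 reads would be 0.484, 0.483 and 0.516 TPM.

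Of 11 antigen presentation genes, 6 were above and 0 below 1 TPM (7 and 0 adjusted over the list alone; 0 below unadjusted), with B2m, the class I light chain, at 5422 ± 384 TPM and Cd74, the class II invariant chain, at 283 ± 260.2 (SD, n = 3). H2-K1 and H2-D1 had 306 ± 187 and 324 ± 89.2 TPM and share near-identical sequence, so the split between them is uncertain. Of 15 immediate early and heat shock genes that tissue dissociation is known to raise, 10 were above and 0 below (11 and 0 adjusted over the list alone; 0 below unadjusted), with Fos at 389 ± 146 TPM, Btg2 at 161 ± 55.8, Nr4a1 at 84.2 ± 29.2 and Dusp1 at 74.9 ± 28.3. Of 12 cell cycle genes, 1 was above and 4 below (1 and 7 adjusted over the list alone): Pcna, which also serves DNA repair, had 62.8 ± 30.1 TPM, while Mki67 had 6, 0 and 7 reads, Cdk1 0, 12 and 4, Ccnb2 1, 0 and 2, and Birc5 0, 2 and 2. Of 10 housekeeping genes, 9 were above and 0 below, also adjusted over the list alone (0 below unadjusted), led by Eef1a1 at 1577 ± 145 TPM, Actb at 1576 ± 477, Rplp0 at 966 ± 438 and Ppia at 796 ± 169.6. Medians of these 4 lists lay at percentile 100, 99.98, 1.75 and 100.

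Within each library 3 pairs of genes were compared on the log2(TPM + 1) scale. Cldn1 exceeded Cldn5, the claudin of endothelium, by 4.71 ± 1.59 (SD, n = 3), and Lepr exceeded Th, which had 0, 1 and 4 reads, by 6.07 ± 2.07, each in 3 of 3 libraries. Slc2a1 exceeded Slc2a4, the insulin-sensitive glucose transporter, by 0.56 ± 0.56, also in 3 of 3 libraries, with 14, 305 and 4 reads against 1, 232 and 3, so that replicate 3 rests on 1 read. Each of the 3 gave p = 0.25 in the exact two-sided sign-flip test, the smallest value 3 libraries allow.

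Replicates matched well for the most abundant genes and poorly below them. Among 67 genes with a mean of at least 1000 TPM, 0 differed more than 4-fold between any 2 libraries, against 532 of 1675 (31.8%) at a mean of at least 100 TPM and 7014 of 10128 (69.3%) at a mean of at least 5 TPM. Across genes, which are not independent replicates, Pearson's r between libraries was 0.685, 0.682 and 0.684 and Spearman's rho 0.563, 0.545 and 0.546 for replicates 1 and 2, 1 and 3, and 2 and 3. Of 9549 genes with at least 100 reads in 1 library, 1582 (16.6%) had none in another. The 5 genes with the largest SD were small RNAs and predicted genes read in 1 library: Mirlet7c-1, Mir7683, Gm25809 and Gm44903 had 530, 203, 166 and 319 reads in replicate 3, against at most 1 elsewhere, and Mir669h had 286 reads in replicate 1 and none elsewhere.

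**Figure D3:**
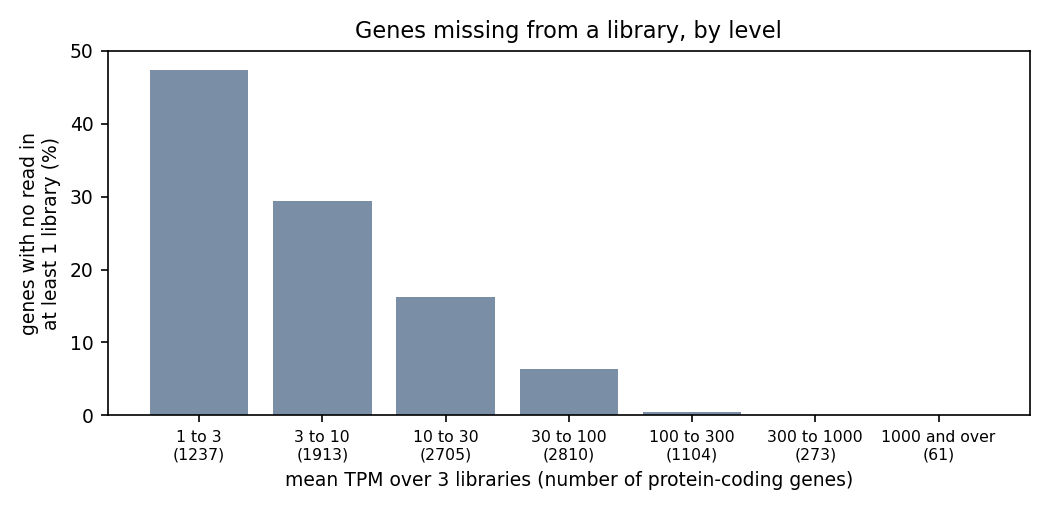
Share of protein-coding genes without a read in at least 1 of the 3 libraries, in percent, by mean TPM, with the number of genes under each bar. The share is 47.4% at a mean of 1 to 3 TPM, 6.41% at 30 to 100 TPM and 0.45% at 100 to 300 TPM.

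As a check of the sex given in the labels, male for all 3 libraries, Xist and 4 Y-linked genes were read. Xist (chromosome X, 103460366 to 103483254, reverse strand), the RNA that silences 1 of the X chromosomes of female cells, had 5835, 8478 and 7140 reads, or 159.6 ± 29.3 TPM (SD, n = 3; limma, adjusted p = 0.00357). The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 0, 1 and 0 reads together, the 1 being on Uty. Of the list's 5 genes, 1 was therefore above 1 TPM, 1 below and 3 without a read (1 and 1 adjusted over the list alone), with its median at percentile 85.94 over 2 genes. Xist overlaps its antisense partner Tsix, which was listed with 26, 0 and 33 reads, and the strand setting of the counting is not given in the sources used here.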

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

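The setting in which no read was added was chosen after the data were seen, and all others before. No paired analysis was possible because the labels give 1 group only. Limma's call counts rested on all 3 libraries: 4519 genes above 1 TPM became 0 to 2451 with 1 replicate left out, and 5092 below became 0 to 5066, where fewer samples left few degrees of freedom (the counts of 0 stood beside 4643 and 4447 genes above and 7852 and 8181 below at an unadjusted p under 0.05). Genes below 1 TPM numbered 0 when genes with a mean under 0.5 TPM were left out (0 unadjusted), which removes them by construction, 0 without mitochondrially encoded genes (6603 unadjusted), 0 at a level of 0.5 TPM (1478 unadjusted), 14063 at 5 TPM and 9834 with a mean-variance trend. Genes above 1 TPM ranged from 3630 to 6496 in the settings that kept all libraries, and 4518 of the 4519 reached 1 TPM in all 3 libraries. With 1 replicate left out, list members above 1 TPM ranged from 0 to 3 for perineurial, 4 for fibroblast, 2 for epineurial, 2 for endoneurial, 1 for neuron, 8 for glial, 1 for endothelial, 2 for mural, 1 for adipocyte, 1 for arachnoid, 2 for tight junction, 6 for adherens and gap junction, 9 for basement membrane, 3 for leptin signalling, 2 for transporter, 1 for receptor, 1 for growth factor, 2 for hedgehog, 3 for cytokine, 3 for antigen presentation, 4 for immediate early, 0 for cell cycle, 6 for housekeeping and 1 for Xist and Y-linked genes. With a trend the perineurial list had 7 members above, the endothelial list 5 and the receptor list 2. A pseudocount of 0.1 gave 5 for the endothelial list. At least 1 TPM in all 3 libraries was reached by 7 perineurial, 9 endothelial and 1 mast cell and neutrophil gene, where no test is made. The perineurial median stayed below the glial median past the threshold in all 9 alternatives run (-6.22 to -4.43, permutation adjusted p from 0.00065 to 0.0185). With genes under 0.5 TPM left out, differences from the epineurial, endoneurial and endothelial lists reversed to -0.78, -3.66 and 0.78, and those from the neuron, macrophage and mast cell lists, at 2.80, 2.61 and 3.77, were no longer past the threshold. That filter leaves fewer genes per list, and it left too few for the lymphocyte and erythroid lists. With 1 replicate left out, differences ranged from 2.08 to 3.65 for neuron, 2.06 to 3.77 for macrophage, 2.35 to 3.95 for lymphocyte and 2.11 to 3.78 for mast cell genes, and each missed the threshold without replicate 2. List means in place of medians brought the adipocyte and erythroid differences, 2.36 and 2.78, past it (permutation adjusted p = 0.0271 and 0.0415), and the cause was not tested. Mean Pearson's r of 0.684 became 0.657 with a pseudocount of 0.1, 0.547 without genes under 0.5 TPM and 0.680 without mitochondrially encoded genes, and ranged from 0.682 to 0.685 with 1 replicate left out. Genes over 4-fold apart numbered 4653 to 4714 with 1 replicate left out, where the mean of at least 5 TPM was taken over the remaining pair, against 7014 over all 3, of which the single pairs gave 4854, 5057 and 4955. Among genes above 1 TPM alone, percentiles were 79.58 for perineurial, 96.37 for fibroblast, 99.99 for endoneurial, 50.5 for endothelial, 19.9 for mural, 67.43 for tight junction, 72.32 for adherens and gap junction, 84.32 for basement membrane, 44.11 for leptin signalling, 52.57 for transporter, 74.88 for growth factor, 64.9 for cytokine, 99.28 for antigen presentation, 55.71 for immediate early and 99.99 for housekeeping genes. That setting cut the lists as well as the background to genes above 1 TPM. The perineurial value thus rests on 4 of 16 genes and the endoneurial value on 3 of 10. The endoneurial, tight junction and growth factor values, 67.56, 25.75 and 23.01 in the main setting, rose with the low members left out. The epineurial, glial and arachnoid lists moved there by no more than the spread between replicates, the other 10 lists had fewer than 3 members above 1 TPM and got no value, and the Xist and Y-linked list, with 2 genes read, got none in any setting. With means in place of medians percentiles were 98.7 for endoneurial, 64.13 for arachnoid, 64.84 for tight junction, 8.26 for receptor and 74.64 for growth factor genes, and the cause was not tested. With 1 replicate left out they ranged from 56.37 to 73.02 for endoneurial, 96.81 to 97.78 for leptin signalling and 60.79 to 91.76 for hedgehog genes. The 3 gene pairs kept their direction in each setting that gave a value, and Lepr against Th, with Th under 0.5 TPM, gave none under that filter. Over the single genes named, 1353 of the calls under an alternative stood on the same side of the threshold, 284 were no longer past it and 63 newly past it, and no called gene turned direction. Depth limits what can be said of genes with few reads, since 1 read on a gene of 1 kb was worth about 0.4 TPM.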

Other observations

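The gene lists in the first paragraphs were added after the data were seen. Of the tests in the later ones, the list-membership test and the test of missing genes by level were planned before their results were seen, and the others were chosen after.

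Lipid synthesis genes were abundant. Of 12 sterol and fatty acid synthesis genes, limma placed 10 above 1 TPM and 0 below (0 below at an unadjusted p under 0.05), and all 12 reached 1 TPM in each library. The desaturases Scd1 and Scd2 had 2564 ± 422 and 1937 ± 174 TPM (SD, n = 3), Hmgcs1, an early enzyme of cholesterol synthesis, 773 ± 179.7, and Elovl6, a fatty acid elongase, 166 ± 24.5. Of 10 glial channel and transporter genes, 8 were above and 0 below (0 unadjusted): the sodium channel Scn7a had 1846 ± 193 TPM, the potassium channel Kcna1 234 ± 90.8, and Kcnj10, a potassium channel of satellite glia, 121 ± 147. Of these 10, 2 are also in lists fixed beforehand. Of 12 genes of neural crest and glial regulation, 6 were above and 0 below (1 unadjusted), with the endothelin receptor Ednrb at 1620.1 ± 626 TPM, Id3 at 901 ± 83.7 and Zeb2 at 170.4 ± 10.6, and 1 of the 12 is also in a list fixed beforehand. Of 10 complement and coagulation genes, 6 were above and 1 below: the regulators Cd59a and Serping1 had 1983 ± 57.6 and 541 ± 178 TPM, and C3, the central complement component, was below with 0, 1 and 0 reads.

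Markers of 4 other cell types of the neck were looked up. Of 7 lymphatic endothelial genes, 2 were above 1 TPM and 2 below; Pdpn, which fibroblasts and perineurial cells also make, had 217 ± 88.8 TPM (SD, n = 3) and Reln 32.2 ± 20.9. Of 6 melanocyte genes limma called 0 above (0 unadjusted), and Dct, whose reads were not recovered, had 100.4 TPM in replicate 3. Of 6 skeletal muscle genes it called 0 above (0 unadjusted), and Mylpf had 369, 3 and 0 reads. Of 6 chromaffin cell genes it called 0 above (0 unadjusted), and Chgb had 1.49 ± 0.227 TPM.

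Glial transcripts stood far above perineurial ones in cells sorted as LepR+, with list medians of 8.57 and 3.31 in log2(TPM + 1) and Fabp7 and Apoe at 14163 and 8934 TPM, and no glial gene of the list is in another list fixed beforehand. Free RNA from lysed ganglion neurons would carry neuronal transcripts along, and the median TPM of the neuron list was at most 0.122% of that of the glial list in any library, which argues against that source. Free RNA from other lysed cells, glia among them, was not tested, since a low neuron list does not bear on it. Glial cells inside the sort gate, which selects for the reporter, and reporter-positive cells that carry glial transcripts themselves cannot be told apart, since either would bring the 12 of 14 glial genes at 1 TPM or more in all 3 libraries, a count known beforehand. Lepr differed by 11.3 times between libraries and the glial median by 1.16 times, but Lepr RNA and the reporter need not move together, and single cells were not measured. With 1 group in the design, no biological explanation was tested.

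Libraries labelled male held Xist reads and almost no Y-linked reads. Too little depth is argued against by the X-linked homologues of the 4 Y-linked genes, Ddx3x, Eif2s3x, Kdm5c and Kdm6a, which had at least 5373 reads together in each library. Cells with more than 1 X chromosome and no Y could account for both sides, with at least 5835 Xist reads and at most 1 Y-linked read per library, which would mean that the sex label does not describe these libraries. Reads of Tsix counted on Xist are argued against by Tsix exons outside Xist, which held at most 2.02% of the reads per kb of Xist in any library. The Y-linked reads, set beside those of the X-linked homologues, argue against cells with a Y chromosome as the source of these 3 libraries. Why the label and the reads differ was not tested, since sex is not a group of the design.

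Of genes with at least 100 reads in 1 library, 16.6% had none in another. A difference in depth is argued against by library totals within 1.076 times of each other. For cell types taken up in different shares, list membership explained 18.1% of the variance of deviations over 85 genes, against a median of 12.8% under permuted membership (permutation p = 0.0726). A p over 0.05 had been set beforehand to count against it, but that bound was dropped after the result was seen, since a missed threshold does not show that shares were equal and the value lay above the permuted median, so this stays open. Few starting cells or transcripts, amplified unevenly, cannot be told apart from it: 6.41% of protein-coding genes at 30 to 100 TPM, with a median of 595 reads, and 47.4% at 1 to 3 TPM lacked a read in a library, but either would give this and a missing library itself lowers a mean, and no biological explanation was tested.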
